A study of Mus musculus with 125 samples.

How the data were processed

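Gene expression was measured in 125 single cells of mouse embryos, each deposited as 1 sample. They comprised 104 primordial germ cells (PGCs) and 21 somatic cells of embryonic days 9.5 to 12.5 (E9.5 to E12.5). Per the labels' protocols, embryos were sexed before their cells were separated, cells of the earlier days were sorted by flow cytometry, and cells from E10.5 on were picked by hand by their GFP signal and size. Day and way of collection therefore change together between E9.5 and E10.5. Polyadenylated RNA of each cell was amplified and sequenced, and no molecular identifiers are named, so that reads copied by PCR are counted singly. Genotypes are XX, XY and XO, and each cell has the strain label C129 or 129C, whose meaning the labels do not spell out.

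The authors deposited 3 tables of genes by cells. The first holds raw counts of reads per gene, not normalised, for 24499 genes. The submitters' processing notes name TopHat2 2.1.1, SAMtools, HTSeq 0.7.2 and the genome build mm10, without stating their roles or whether strand was used in counting. Reads of Xist and of its antisense partner Tsix, which has counts of its own, can therefore not be told apart where the genes overlap. The second table is the deposited allelic ratio, a fraction between 0 and 1 for 13639 genes. Which allele it refers to, and how many reads lie behind each value, is not given in the sources used here. The ratio ran over 0.5 on average for X-linked genes in all 125 cells, while for autosomal genes it ran under 0.5 in 27 cells. Whether it refers to the same parental allele in every cell is therefore open. The third holds values per gene that the authors call RPRT, for 18803 genes. Its scaling is not spelled out. The CPM of a cell divided by its RPRT value gave a length of 1.49 to 1.91 kb for Actb but of 0.081 to 17.927 kb for Xist. What the values are scaled by therefore stays open. RPRT was treated as a unit of its own and used only as an alternative measure of the X-linked share.

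Gene symbols were matched to GENCODE M21 (GRCm38, the assembly of mm10) for 23680 genes and to RefSeq for 734. The 85 unmatched genes held 0.0357% of all counts and were left out of chromosome groups. This gave 1068 X-linked genes, 483 of them with allelic ratios, and 23293 autosomal genes, and 3 pseudoautosomal genes were left out of the X-linked group. Total counts per cell ran from 235529 to 43753766 (median 3093546), with 3800 to 12020 genes detected. No cell was removed. The median Spearman correlation between cells was 0.696, and 4 libraries that correlated above 0.9 with each other are treated in the closing section.

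A pair of a gene and a cell was informative when it had an allelic ratio and a count of at least 20, and biallelic when the less frequent allele held a share of at least 0.15. This measure does not depend on which X chromosome is silent in a cell. Of 387346 pairs with a ratio 376772 were informative, and 1.87% of all pairs had a ratio at a count of 0. Shares are given with exact Clopper-Pearson 95% intervals and the standard deviation (SD) over cells. XX PGCs were set against XY PGCs and against XX somatic cells over the 4 days with an exact two-sided paired permutation test, which cannot give a p below 0.125. Single genes needed at least 5 informative XX PGCs at each day compared, and bins spanned 10 Mb. Relations of the biallelic share with expression, position and distance to Xist were tested across genes with a circular shift along the chromosome. Genes of 1 chromosome are not independent replicates. X-linked dosage was the share of autosomal plus X-linked counts that is X-linked, averaged over cells.

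For differential expression, cells are not replicates, and the labels name no embryo. The counts of all cells of a group were therefore summed into 1 sample, and the 4 days served as replicates or as a trend. The quasi-likelihood F test of edgeR 4.0.16 was run on these sums in R 4.3.3 with filterByExpr, TMM scaling and a Benjamini-Hochberg adjusted p below 0.05. The comparisons were the change per day in C129 PGCs with genotype as a covariate (8 sums), PGCs against somatic cells of XX embryos with day as a factor (8 sums), XY against XX PGCs with day as a factor (8 sums), and the difference of the change per day between XY and XX PGCs. TMM set the median of all genes at 0.70 (log2) in PGCs over somatic cells, against 0.35 with DESeq2's size factors in edgeR and -0.35 in DESeq2. In XY over XX PGCs this median was -0.25, -0.24 and -0.11. The comparisons of 129C with C129 XX PGCs and of XO with XX PGCs at E12.5 had 1 sum on each side and no test. They are given as CPM ratios with exact conditional binomial intervals. Gene groups are given as the percentile of their median among 10000 random lists of autosomal genes matched on expression. A sum of 0 was set to a floor of 3 counts over the group.

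The 19 gene lists fixed in advance were germ cell specification, the pluripotency network, methylation-sensitive germline genes, meiotic prophase, male germ cell differentiation, DNA methylation and demethylation enzymes, X inactivation and silencing factors, known escape genes, Y-linked genes, imprinted genes, cell cycle, glycolysis, immediate early and stress genes, and markers of gonadal somatic and mesenchymal cells, supporting cells of the gonad, endothelium, blood cells, gut and epithelial cells and neural cells. All X-linked genes, with and without Xist and the escape genes, were added as groups. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Its Benjamini-Hochberg adjustment ran over the lists of a comparison.

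Genes were named by a fixed rule. It took the 8 largest changes in each direction among genes with an adjusted p below 0.05, a mean CPM of at least 10 and the same direction on all days, and up to 4 members of each list with the lowest p. It also took the 8 X-linked genes with the largest gain in biallelic share, the 8 with the lowest share at E12.5, the known escape genes, Xist, Tsix and the Y-linked genes. In comparisons without a test it took the 5 largest ratios in each direction among genes with at least 50 CPM in the higher sum, counts in at least 50 percent of its cells and an interval that excludes 1. Groups, comparisons, tests, lists and this rule were set before the data were examined, as were the alternatives except 22 named as added in the closing section.

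The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, mean CPM over cells in limma with a pseudocount of 1 or 5, day as a factor, XY groups added to the lineage comparison, each day or cell left out, other minimum allele shares and counts, other measures of dosage, and doubted libraries left out. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The edgeR fits, camera, the biallelic calls and the circular shift were tested on simulated data, and the other steps were not. The 200 changed genes of each run were drawn from genes of the real table with a mean CPM of at least 10, so recovery of weaker genes was not measured. Among the changed genes, the change per day was recovered for 5.5, 73 and 89% at 2-, 4- and 8-fold per day. The lineage difference was recovered for 0, 21 and 70% at 4-, 16- and 64-fold. The genotype difference was recovered for 3, 62 and 91.5% at 4-, 16- and 64-fold, and its change per day for 0.5, 11.5 and 61.5% at 2-, 4- and 8-fold. Simulated biallelic shares of 2, 20 and 50% were measured as 2.20, 20.1 and 50.2%, and the circular shift called 3.5% of 200 simulated runs without a relation. The simulated ratios lay clear of the threshold and no reads were drawn. These shares therefore check the calculation, not how well biallelic genes are found in these libraries. Somatic XY groups entered a test only in the alternative that adds the XY groups to the lineage comparison, and the XO somatic cell was given only as values. The text prints part of the genes that the rule names, and 1 result is not reported here.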

Results

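Transcriptomes of 104 primordial germ cells (PGCs) and 21 somatic cells of mouse embryos were measured from E9.5 to E12.5, the days over which PGCs, the precursors of eggs and sperm, migrate to the gonad and settle there. The series asks when genes of the silenced X chromosome return to expression in the germline and where silencing is kept. XX PGCs with the strain label C129 numbered 18 at E9.5, 8 at E10.5, 20 at E11.5 and 20 at E12.5, and XY PGCs 7, 8, 3 and 9. Somatic cells of XX embryos numbered 5, 5, 3 and 3, and those of XY embryos 3 at E11.5 and 1 at E12.5. With the strain label 129C there were 8 XX PGCs, 3 PGCs with 1 X chromosome and no Y (XO) and 1 XO somatic cell, all of E12.5. Total counts ran from 235529 to 43753766 per cell with a median of 3093546. The labels name no embryos, so the cells of a group were summed into 1 sample, and p-values measure only the spread between sums of different days, which may be technical. Summed counts ran from 4599162 to 176300586 in the groups tested, and the largest cell held 18.5 to 76.0% of a sum. Reads were copied by PCR without molecular identifiers, so all intervals and floors cover counting error only. Cells of E9.5 were collected in another way than those of later days, so day and collection cannot be told apart there, and values without E9.5 are given where they differ.

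X-linked genes were read from 1 allele in nearly all XX PGCs at E9.5 and from both alleles in many at E12.5. Of all pairs of an X-linked gene and an XX PGC, 3.47% were biallelic at E9.5 (50 of 1443 pairs, exact 95% interval 2.58 to 4.54%, SD over cells 3.65). The share was 11.96% at E10.5 (75 of 627 pairs, 9.53 to 14.8%, SD 6.69), 30.5% at E11.5 (655 of 2148 pairs, 28.6 to 32.5%, SD 14.1) and 39.7% at E12.5 (486 of 1225 pairs, 36.9 to 42.5%, SD 18.98). Single cells of E12.5 lay between 10.3 and 83.3%. In XY and XO PGCs, which have 1 X chromosome and so give the background, 10 of 2717 pairs in 30 cells were biallelic (0.368%), with no group above the 1.25% of XO PGCs (2 of 160 pairs). Somatic cells of XX embryos, which as a rule keep 1 X chromosome silent, stood at 1.79% (5 of 280), 5.23% (16 of 306), 1.46% (4 of 274) and 4.65% (8 of 172) on the 4 days. Xist reached 10 CPM in 4 of 5, 2 of 5, 2 of 3 and 3 of 3 of them. The XX somatic replicates 46 of E9.5 and 34 of E10.5, with 0 and 0.225 CPM of Xist, held Y-linked counts. In XY somatic cells 3 of 155 pairs were biallelic at E11.5 and 0 of 135 at E12.5 (exact 95% interval up to 2.70%), and 0 of 25 in the XO somatic cell (up to 13.7%).

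Autosomal genes of the same XX PGCs were biallelic in 33.7, 38.4, 46.1 and 50.8% of pairs on the 4 days, which sets the level that genes with both copies active reach in these libraries. The X-linked share was 0.103 of the autosomal share at E9.5, 0.312 at E10.5, 0.662 at E11.5 and 0.782 at E12.5. With autosomal pairs drawn to the counts of the X-linked pairs, the ratio ran from 0.098 to 0.752. Over the 4 days, XX PGCs exceeded XY PGCs by 21.03 percentage points (SD 16.4, n = 4 days, higher on 4 of 4; exact two-sided paired permutation p = 0.13, the smallest this design allows). XX PGCs exceeded XX somatic cells by 18.1 points (SD 16.4, n = 4 days, higher on 4 of 4, exact p = 0.13). Without E9.5 the differences were 26.95 and 23.6 points, higher on 3 of 3 days (exact p = 0.25, the smallest possible). Of the 90 XX-labelled libraries, 55 held any counts of 4 Y-linked genes and 9 at least 20 counts and 10 CPM of them (11.5 to 785 CPM). Of the 30 libraries of E9.5, 13 had uneven autosomal ratios, all labelled XX and including all 5 somatic cells of that day. Where a cell carries 1 parental allele alone, a gene cannot be read as biallelic even with both copies active. Without these 13 libraries the share in XX PGCs of E9.5 was 4.09%. Without these, the 9 libraries with Y-linked counts and 4 libraries that closely resemble each other, the share in XX PGCs was 6.01% at E9.5 (25 of 416 pairs in 5 cells) and 15.01% at E10.5. When every ratio of at most 0.85 was counted, a measure chosen after the data were seen, XX somatic cells of E9.5 stood at 25.4% above XX PGCs at 8.11%, and the difference from somatic cells was 18.8 points with 3 of 4 days higher (exact p = 0.375).

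**Figure D1:**
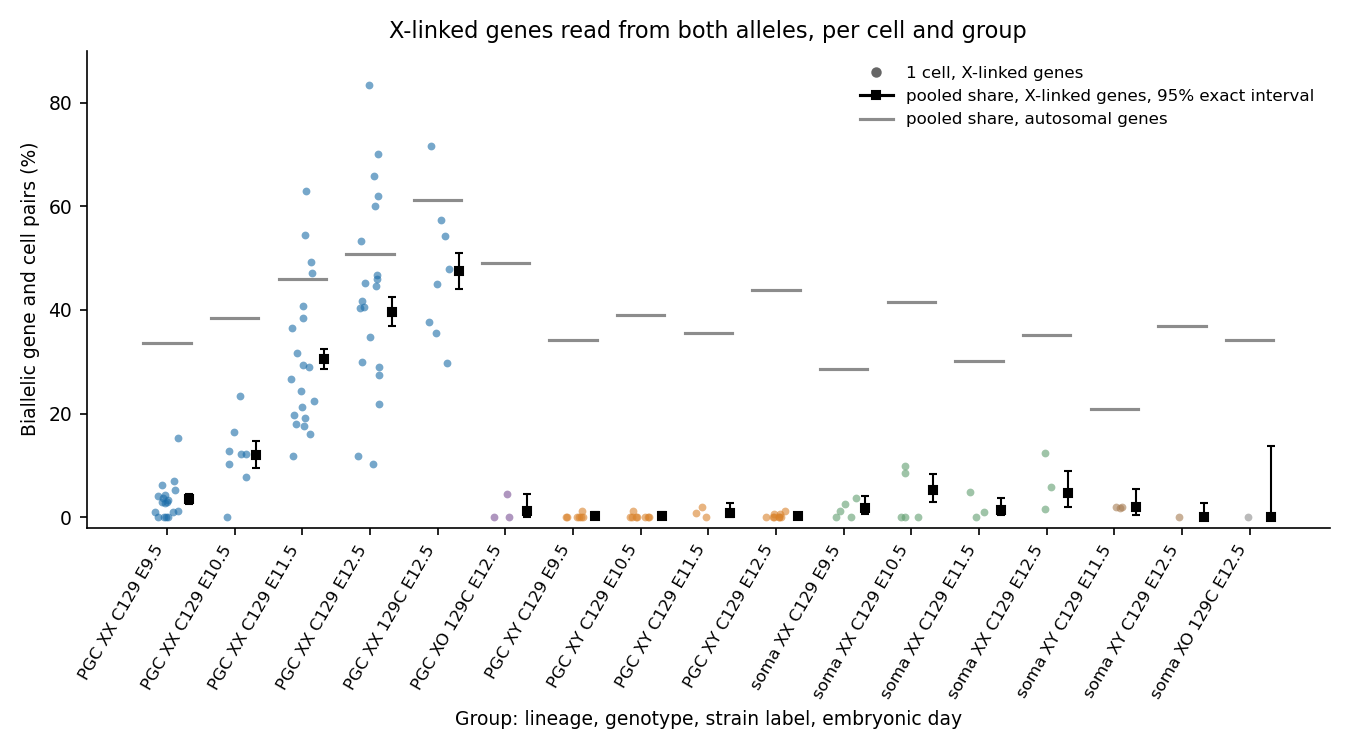
Share of X-linked gene and cell pairs that were biallelic (vertical axis, percent) for each of the 17 groups, with 1 point per cell, a square for the pooled share with its exact 95% interval, and a grey line for the autosomal genes of the same cells. The pooled share of XX C129 PGCs lay at 3.47% at E9.5 and 39.7% at E12.5, and that of XY PGCs at no more than 0.755%.

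Single X-linked genes differed widely in the share of XX PGCs that expressed both alleles. Among 76 genes with at least 5 informative XX PGCs at both E9.5 and E12.5, 55 were biallelic in no cell at E9.5. At E12.5 the share was higher for 68 genes, equal for 4 and lower for 4, and the median over genes was 0% at E9.5 and 50% at E12.5. The 18 XX PGCs of E9.5 include libraries with uneven autosomal ratios or Y-linked counts, which may be unable to show both alleles. Without all doubted libraries 5 cells remain. The E9.5 shares of single genes, bins and escape genes were not measured without them, and some low values may stem from these libraries. The largest differences were those of Bcap31, a membrane protein of the endoplasmic reticulum (X, 73686178 to 73716175 in GRCm38), biallelic in 0 of 15 cells at E9.5 and 11 of 11 at E12.5 (exact 95% interval from 71.5%), and Rps4x, a ribosomal protein (102184941 to 102189394), in 0 of 18 and 17 of 17. Reads of Rps4x may be shared with its processed copies, though it was biallelic in 0 of 30 informative XY and XO PGCs. Smc1a, a subunit of cohesin (152016428 to 152062694), was biallelic in 0 of 13 and 11 of 12 cells, and Idh3g, a subunit of mitochondrial isocitrate dehydrogenase (73778963 to 73786897), in 0 of 17 and 13 of 15. The tRNA methyltransferase gene Ftsj1 (8238668 to 8252406) was biallelic in 0 of 12 and 10 of 12 cells, and Plp2 (7667941 to 7671390) in 1 of 18 and 7 of 8. Alg13, which acts in protein glycosylation (144317804 to 144374450), stood at 0 of 12 and 5 of 6 cells, and the ubiquitin ligase gene Siah1b (164070705 to 164076493) at 0 of 5 and 5 of 6.

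The following 8 X-linked genes were biallelic in no more than 1 C129 XX PGC at E9.5 and at E12.5. Hnrnph2, an RNA-binding protein (134601179 to 134607060), was biallelic in 0 of 11 cells at E9.5 and 0 of 7 at E12.5 (exact 95% interval up to 40.96%). The transcription factor gene Klf8 (153237466 to 153396132) stood at 0 of 9 and 0 of 7 cells, and Hmgn5, which binds nucleosomes (109004534 to 109013404), at 0 of 17 and 0 of 6. Amot (145446425 to 145505181) was biallelic in 1 of 11 and 0 of 6 cells, and Pola1, the catalytic subunit of DNA polymerase alpha (93304767 to 93632155), in 1 of 8 and 0 of 5. Rbmx2 (48695004 to 48710723) stood at 0 of 5 at both days, AU015836 (93968659 to 93975470) at 0 of 16 and 1 of 11, and the mitochondrial thioesterase gene Acot9 (155262443 to 155297654) at 0 of 7 and 1 of 9. At E11.5, Rbmx2 was biallelic in 3 of 9, Hmgn5 in 3 of 15 and Acot9 in 2 of 11 cells, and the other 5 in none. In 129C XX PGCs of E12.5, Acot9 was biallelic in 4 of 6 and Rbmx2 in 2 of 4 cells, and the others in none of 2 to 7 cells. At a minor allele share of 0.10, Acot9 stood at 33.3% in C129 XX PGCs of E12.5. With 5 to 11 cells per gene at E12.5, a share of 0 still allows up to 52.2% for the genes with 5 cells. Of the 76 genes measured at both days, from which these 8 were taken, 6 were biallelic in no cell at E12.5. Among all 99 X-linked genes measured at E12.5, 16 (16.2%) were biallelic in no cell, against 224 of 3328 autosomal genes (6.73%). The medians were 44.4 and 54.5%. The autosomal genes were not matched to the X-linked ones on expression or informative cells, so these shares do not single out the genes named. Across these 99 genes, the biallelic share went with expression (Spearman rho = 0.477, Pearson r = 0.366 with mean CPM; circular shift permutation p = 0.0101, the smallest the shifts can give, adjusted p = 0.0303 over 3 relations). The adjusted p was 0.05 when at least 8 cells were asked for and 0.0197 with at least 3. With at least 8 cells the permutation p of 0.0167 was again the smallest that the 60 shifts can give. Autosomal genes showed a rank correlation with expression of 0.487 in the same cells. The relation with distance to Xist (rho = 0.11, r = 0.117, permutation p = 0.606, adjusted p = 0.697) and with position along the chromosome (rho = -0.061, r = -0.074, adjusted p = 0.697) did not pass the test.

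Along the X chromosome, the biallelic share was higher at E12.5 than at E9.5 in all 14 bins of 10 Mb with at least 10 pairs at both days. The bin from 130 to 140 Mb, which holds Hnrnph2, was lowest at E12.5 with 8 of 60 pairs (13.3%, exact 95% interval 5.94 to 24.6%), after 1.02% at E9.5 and 16.03% at E11.5. It was followed by 140 to 150 Mb with 20% of 25 pairs and 40 to 50 Mb with 21.2% of 33 pairs. Of the bins with at least 20 pairs, the highest were 20 to 30 Mb with 52.6% (40.8 to 64.2%), 10 to 20 Mb with 50.6%, and 100 to 110 Mb, which holds Xist and Rps4x, with 47.1%. With bins of 5 Mb the lowest share was 5.56%, from 95 to 100 Mb. Bins were not tested against each other.

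**Figure D2:**
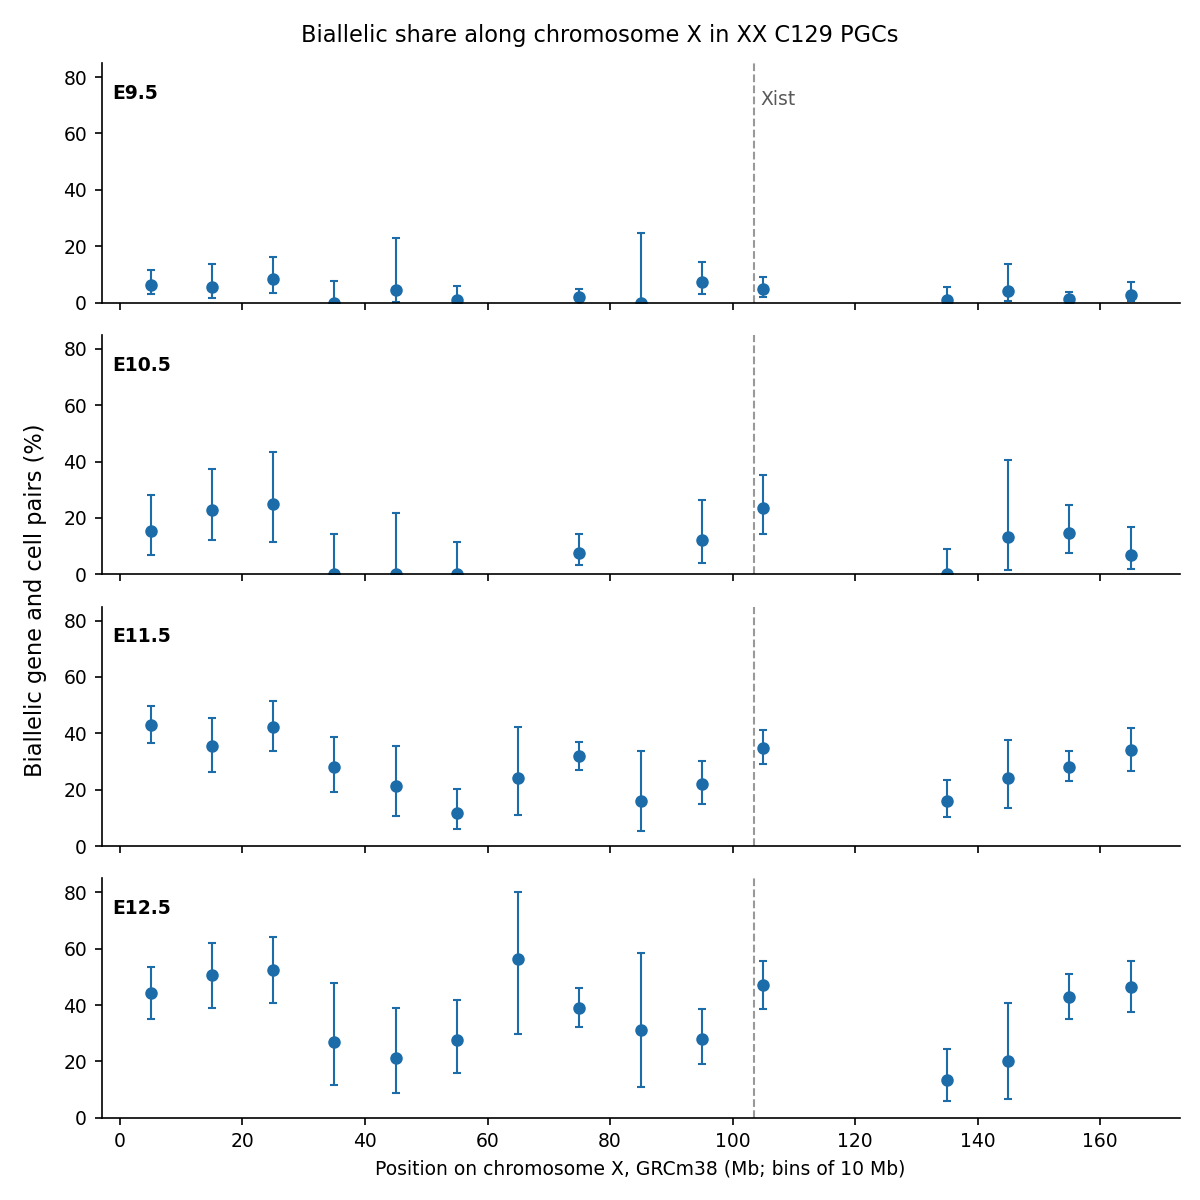
Biallelic share of X-linked pairs in XX C129 PGCs (vertical axis, percent) in bins of 10 Mb along the X chromosome (horizontal axis, Mb), 1 panel per day, for bins with at least 10 pairs, with Xist marked by a dashed line. At E12.5 the bin from 130 to 140 Mb lay lowest at 13.3% and the bin from 20 to 30 Mb at 52.6%.

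Genes known to escape X inactivation in mouse tissues were in part biallelic already at E9.5. Together they stood at 19.5% in XX PGCs of E9.5 (16 of 82 pairs, exact 95% interval 11.6 to 29.7%), 36.4% at E10.5, 50.8% at E11.5 and 56.0% at E12.5 (44.7 to 66.8%). The translation factor gene Eif2s3x (94188707 to 94212862) was biallelic in 46.2% of cells at E9.5 and 75% at E12.5. The RNA helicase gene Ddx3x (13280970 to 13294052) stood at 7.14 and 75%, the deubiquitinase gene Usp9x (13071498 to 13173328) at 0 and 68.8%, and Utp14a (48256862 to 48282453) at 14.3 and 71.4%. The listed transcript 1810030O07Rik (12654879 to 12673668) stood at 42.9 and 25%, and it was biallelic in 2 of 9 informative XY and XO PGCs. In XX somatic cells escape genes were biallelic in 4.55, 7.14, 11.8 and 9.09% of 11 to 22 pairs a day, and in XO PGCs in 0 of 13 (up to 24.7%). The X-linked share of XX PGCs of E9.5 was 2.50% with the escape genes left out.

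XX PGCs devoted a larger share of their counts to X-linked genes than XY PGCs on each day. The share was 3.08% (SD over cells 0.330), 3.33% (SD 0.503), 3.51% (SD 0.366) and 3.51% (SD 0.372) from E9.5 to E12.5 in XX PGCs, and 2.85% (SD 0.250), 2.81% (SD 0.333), 2.53% (SD 0.524) and 2.73% (SD 0.283) in XY PGCs. The ratio of XX to XY was 1.08 at E9.5, 1.18 at E10.5, 1.39 at E11.5 and 1.29 at E12.5, with a mean of 1.23 (log2 0.30, SD 0.16, n = 4 days; exact two-sided paired permutation p = 0.13, the smallest possible). At E12.5, 129C XX PGCs stood at 3.66% and XO PGCs at 2.68%. With the authors' RPRT values the mean ratio was 1.19, with 0.988 at E9.5 (exact p = 0.25, higher on 3 of 4 days). Xist, the RNA that coats the inactive X chromosome, had a median of 626, 0.225, 899 and 1478 CPM over XX somatic cells of the 4 days and of 0, 0, 0.0752 and 4.99 CPM over XX PGCs. Tsix, the antisense partner of Xist, had 14 counts in C129 XX, 4 in 129C XX and 3 in XO PGCs of E12.5, and without strand its reads cannot be told from those of Xist where the genes overlap.

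Over the 4 days, PGCs gained expression of germline and meiotic genes and lost expression of glycolytic genes. The slope tested was common to XX and XY PGCs, and no list was tested within a genotype. The methylation-sensitive germline genes, whose promoters are silenced by DNA methylation in other tissues, rose as a group (22 genes, camera adjusted p = 1.57e-15; adjusted p = 0.0128 with an estimated correlation), and 9 of them passed edgeR's test adjusted over the list alone. Dazl, an RNA-binding protein that germ cells need, went from 1.05 to 1694 CPM in XX PGCs and from 0.184 to 1404 CPM in XY PGCs between E9.5 and E12.5 (log2 change per day 3.75 ± 0.69 SE, n = 8 sums). The RNA helicase gene Ddx4 went from 43.1 to 1008 CPM in XX PGCs (1.12 ± 0.24 per day), and Asz1, which acts in transposon control, from 8.56 to 181 CPM. In XY PGCs Ddx4 went from 97.25 to 553.7 CPM and Asz1 from 4.292 to 264.5 CPM. Brdt, a testis bromodomain protein, stood at 0.0115 CPM in XX PGCs of E9.5 and 14.98 CPM at E12.5, and at 12.81 CPM in XY PGCs of E12.5. Meiotic prophase genes also rose (15 genes, camera adjusted p = 6.00e-09; adjusted p = 0.0128 with an estimated correlation), 7 of them adjusted over the list alone. The cohesin gene Smc1b went from 0.212 to 487 CPM in XX PGCs and from 2.43 to 151 CPM in XY PGCs (2.74 ± 0.53 per day). Meioc (3.37 and 9.078 CPM), Tex12 (8.04 and 3.811 CPM) and Sycp2 (3.10 and 5.116 CPM) were still low in XX and XY PGCs of E12.5.

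Glycolysis genes fell (15 genes, camera adjusted p = 7.95e-10; adjusted p = 0.0341 with an estimated correlation), 9 of them adjusted over the list alone. The glucose transporter gene Slc2a3 went from 692 to 77.3 CPM in XX PGCs and from 752 to 34.4 CPM in XY PGCs (-1.55 ± 0.26 per day). Ldha, which makes lactate, changed by -1.23 ± 0.20, Pgk1 by -0.70 ± 0.17 and Pfkl by -0.96 ± 0.28 per day. Cell cycle genes fell at the preset correlation (21 genes, adjusted p = 5.42e-04; adjusted p = 0.194 with an estimated correlation), with Mcm4 at -0.68 ± 0.20 and Ccnd3 at -0.60 ± 0.21 per day. The adjusted p was 0.0549 without E12.5. Immediate early and stress genes fell (11 genes, adjusted p = 0.0216; adjusted p = 0.343 with an estimated correlation), with Fos at 507 and 44.9 CPM in XX PGCs, and the call was lost without E9.5 (adjusted p = 0.802). Markers of gonadal somatic and mesenchymal cells rose in the same sums (17 genes, adjusted p = 1.47e-05; adjusted p = 0.230 with an estimated correlation), 8 of them adjusted over the list alone. Wt1 went from 0.00573 to 13 CPM in XX PGCs, Gata4 from 0.00573 to 30.9 CPM, and the collagen gene Col1a2 from 0.0388 to 85.8 CPM in XY PGCs. Neural markers rose too (8 genes, adjusted p = 0.0345; adjusted p = 0.194 with an estimated correlation), 3 of them adjusted over the list alone, among them Pax6 with 18.1 CPM and Nes with 20.8 CPM in XX PGCs of E12.5. The call was lost without E9.5, E10.5 or E12.5 (adjusted p = 0.243, 0.126 and 0.0548).

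No call was made for germ cell specification (13 genes, adjusted p = 0.231), the pluripotency network (14 genes, 0.790), male germ cell differentiation (8 genes, 0.105), DNA methylation and demethylation enzymes (10 genes, 0.790, median up and test down), known escape genes (16 genes, 0.358, median down and test up), Y-linked genes (5 genes, 0.981) or imprinted genes (28 genes, 0.617). The same held for endothelium (8 genes, 0.695), blood cells (5 genes, 0.617, median up and test down; 0.00372 with the test up without E12.5, in a range of 0.00372 to 0.790), gut and epithelial cells (7 genes, 0.221), and X-linked genes with or without Xist and escape genes (459 and 444 genes, both 0.617). Too few supporting cell markers were expressed to be tested by day. X inactivation and silencing factors had an adjusted p of 0.0762 (25 genes), which was 0.0227 with lower levels without E9.5, in a range of 0.00847 to 0.174 over the alternatives. Male germ cell differentiation passed with higher levels without E10.5 (adjusted p = 0.0159, range 0.0159 to 0.510). Among single genes, 0 of 12133 passed the test of edgeR over all genes tested, while 1117 had an unadjusted p under 0.05. DESeq2 called 1538 genes (1214 higher and 324 lower), and limma on mean CPM over cells called 1, Dazl (adjusted p = 0.137 in edgeR, range 1.99e-09 to 0.561 over the alternatives). The pluripotency gene Pou5f1 changed by -0.45 ± 0.18 and Tfap2c by -0.75 ± 0.24 per day, and imprinted Igf2 by 2.44 ± 0.74. X-linked Kdm5c changed by 1.14 ± 0.42 and Xist by 0.93 ± 0.56 per day, none of them past the threshold.

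**Figure D3:**
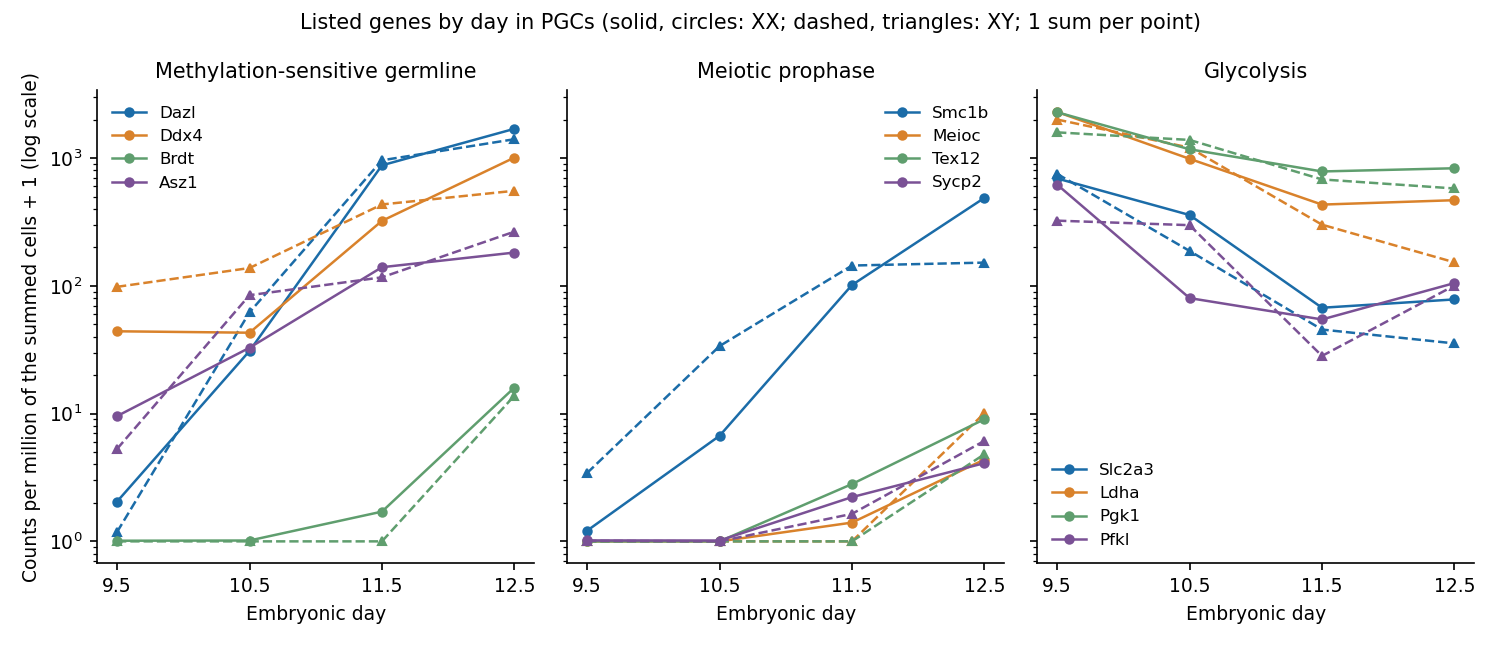
Expression of 12 genes of the germline, meiotic and glycolysis lists in the summed PGCs of each day (horizontal axis, embryonic day; vertical axis, CPM + 1 on a log scale), with solid lines for XX and dashed lines for XY PGCs. Dazl stood at 1.05 CPM in XX PGCs of E9.5 and 1694 CPM at E12.5, and Slc2a3 at 692 and 77.3 CPM.

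PGCs of XX embryos expressed germ cell and pluripotency genes that somatic cells of the same days nearly lacked. Germ cell specification genes were higher in PGCs (13 genes, camera adjusted p = 2.85e-11; adjusted p = 0.191 with an estimated correlation), with 6 passing over all genes tested and 12 adjusted over the list alone. The transcription factor genes Prdm14 (log2 8.68 ± 1.44 SE, n = 4 days, edgeR adjusted p = 0.00869) and Tfap2c (8.58 ± 1.09, adjusted p = 0.00165) had 109 to 401 and 329 to 543 CPM in PGCs and no more than 1.93 CPM in somatic cells. Dnd1, which protects germ cell RNAs, differed by 8.54 ± 1.26. Pluripotency genes were higher as well (14 genes, adjusted p = 3.21e-11; adjusted p = 0.191 with an estimated correlation; 7 over all genes and 10 adjusted over the list alone), among them Pou5f1 (8.18 ± 1.07, adjusted p = 0.00208), Esrrb (8.13 ± 1.25), Zfp42 (8.19 ± 1.32) and Utf1 (8.53 ± 1.38). Methylation-sensitive germline genes were higher (23 genes, adjusted p = 7.03e-13; adjusted p = 0.233 with an estimated correlation; 7 over all genes and 17 adjusted over the list alone), among them the piRNA factor gene Piwil2 (7.91 ± 1.46) and Tex19.1 (7.91 ± 1.41). Meiotic prophase genes (15 genes, adjusted p = 2.71e-04; adjusted p = 0.233 with an estimated correlation; 1 and 2) and male germ cell differentiation genes (8 genes, 0.00231; adjusted p = 0.191 with an estimated correlation; 1 and 2) were also higher, with the cohesin gene Stag3 and the Tudor domain gene Tdrd5 passing over all genes.

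Somatic cells exceeded PGCs in Xist (PGCs over somatic cells -8.58 ± 1.04, adjusted p = 0.00117), with 38 to 1950 CPM in their sums against 0.124 to 2.69 CPM. Markers of gonadal somatic and mesenchymal cells were higher in somatic cells (22 genes, adjusted p = 7.03e-13; adjusted p = 0.191 with an estimated correlation; 2 over all genes and 9 adjusted over the list alone), with the intermediate filament gene Vim at -4.67 ± 0.69 (adjusted p = 0.00409) and Col1a2 at -7.52 ± 1.27. Supporting cell markers were likewise higher there (6 genes, adjusted p = 5.38e-05; adjusted p = 0.191 with an estimated correlation; 4 adjusted over the list alone). Imprinted genes were lower in PGCs (30 genes, adjusted p = 1.19e-05; adjusted p = 0.206 with an estimated correlation), 3 of them over all genes, namely Grb10 (-3.77 ± 0.80), Gnas (-4.69 ± 1.04) and Nnat (-9.64 ± 2.13), and 9 lower and 1 higher adjusted over the list alone. Endothelium markers were higher in PGCs (7 genes, adjusted p = 0.0331; adjusted p = 0.348 with an estimated correlation; 4 adjusted over the list alone), led by Pecam1 (7.11 ± 1.66), an adhesion protein that pluripotent cells express too. This call was lost without E9.5 (adjusted p = 0.401), without E11.5 (0.307) and with the XY groups added (0.701).

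Among all genes, 56 were higher and 62 lower in PGCs of 12967 tested, and 2256 had an unadjusted p under 0.05. The split was 33 and 71 with DESeq2's size factors in edgeR. Leaving out E10.5, E12.5, E9.5 or E11.5 gave 61, 65, 93 and 198 genes, and without all doubted libraries 122 genes passed, 75 of them shared. Largest among the higher were Zscan10, a pluripotency factor gene (10.19 ± 1.82), the kinase gene Jak3 (9.23 ± 2.05), St6galnac2 (8.82 ± 1.89), Zc3hav1 (8.73 ± 1.78), Enpp3 (8.68 ± 1.64) and Pls1 (8.64 ± 1.76). Fez1 had 0 counts in PGCs and 1817 in somatic cells, at least 4827-fold lower against a floor of 3 counts over the group. The cadherin gene Dchs1 (-12.12 ± 1.66, adjusted p = 0.00295) and Wls, which secretes Wnt proteins (-12.06 ± 1.26, adjusted p = 2.29e-04), followed, with Sobp, Tril, Antxr2, Spon1 and the X-linked collagen gene Col4a5. Prdm14, Tfap2c, Dnd1, Pou5f1, Esrrb, Zfp42, Utf1, Xist, Vim, Col1a2, Dchs1, Wls and Spon1 passed in all 12 alternatives. The calls of Zscan10, Jak3, St6galnac2, Zc3hav1, Enpp3, Pls1, Stag3, Tdrd5, Fez1, Sobp, Tril, Col4a5, Piwil2, Grb10, Gnas, Nnat, Tet3 and Pcgf5 were lost without E10.5, with adjusted p up to 0.221 for St6galnac2. Of these, all but Zscan10, Pls1, Piwil2 and Grb10 were also lost without E9.5, as was Ccnd2 (0.0541), and all but Zscan10, Enpp3, Fez1, Sobp and Tet3 without E12.5, as was Tex19.1 (0.0636). Sobp (0.153), Tet3 (0.140) and Tdrd5 lost theirs without E11.5, and Antxr2 (0.0761) with the XY groups added. Of the X-linked genes, 4 were higher and 6 lower of 501, and neither these nor the 486 without Xist and escape genes differed as a group (adjusted p = 0.992 each). No call was made for DNA methylation enzymes (11 genes, 0.945, median up and test down, Tet3 lower at -10.81 ± 2.34), X inactivation and silencing factors (25 genes, 0.405, Pcgf5 higher at 7.96 ± 1.72), known escape genes (16 genes, 0.945), Y-linked genes (3 genes, 0.651), cell cycle (21 genes, 0.945, Ccnd2 lower at -7.08 ± 1.24) or glycolysis (15 genes, 0.505, mean up and test down; 2 higher and 4 lower adjusted over the list alone). The same held for stress genes (11 genes, 0.651), blood cells (6 genes, 0.266, but 0.00522 and lower in PGCs without E11.5), gut (9 genes, 0.266) and neural cells (9 genes, 0.405).

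**Figure D4:**
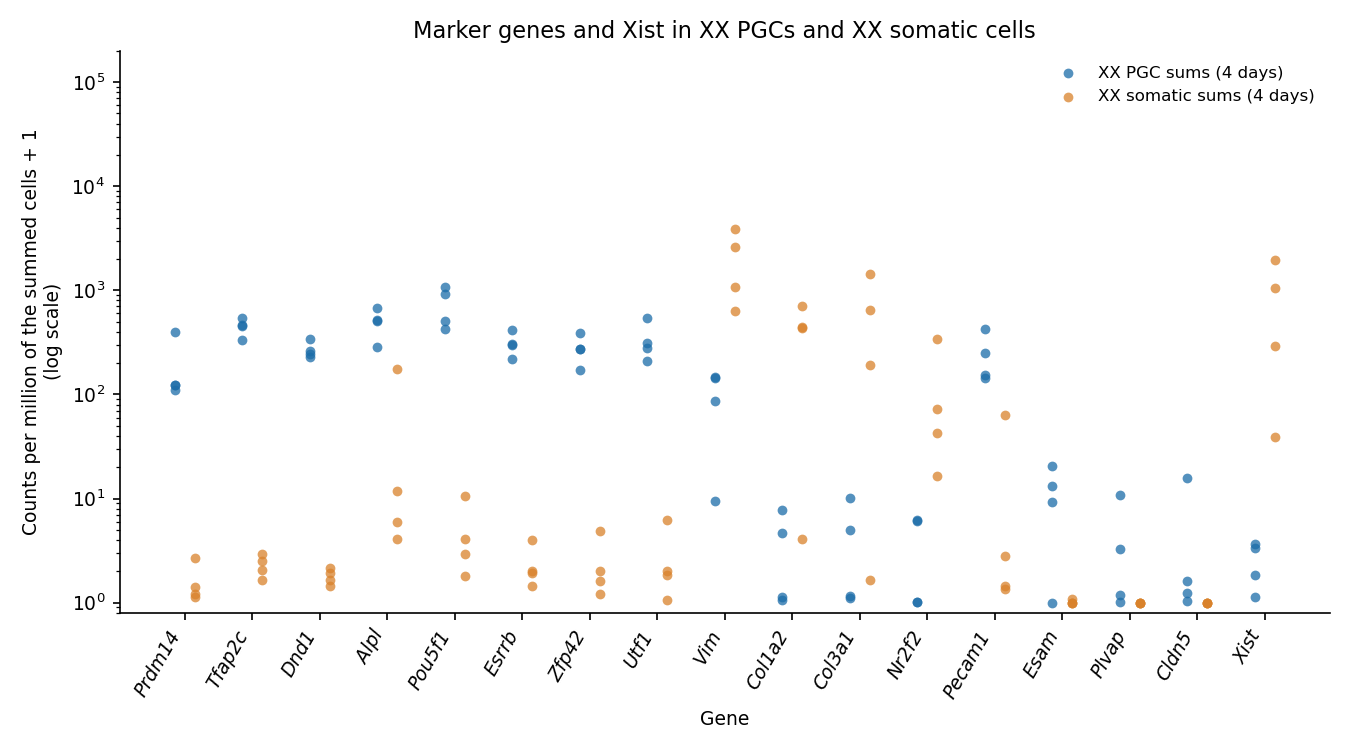
Expression of marker genes and Xist in the 4 XX PGC sums and the 4 XX somatic sums (vertical axis, CPM + 1 on a log scale), 1 point per day. Tfap2c ran from 329 to 543 CPM in PGC sums and reached 1.93 CPM in somatic sums, and Xist ran from 38 to 1950 CPM in somatic sums and reached 2.69 CPM in PGC sums.

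XY and XX PGCs differed in Y-linked genes and in no other list. Y-linked genes were higher in XY PGCs (5 genes, camera adjusted p = 1.92e-08; adjusted p = 0.762 with an estimated correlation; 3 adjusted over the list alone). The translation factor gene Eif2s3y had 190 to 616 CPM in XY sums and 0.159 to 28.2 CPM in XX sums (log2 7.40 ± 1.64, n = 4 days), and the helicase gene Ddx3y 4.87 to 42.1 against 0.034 to 1.14 CPM. Uba1y, which starts ubiquitin transfer, was higher in XY sums on 3 of 4 days, with 0.0583 CPM in XY and 0.390 CPM in XX PGCs of E9.5. Eif2s3x, the X-linked counterpart of Eif2s3y, was lower in XY PGCs on 4 of 4 days (-1.30 ± 0.45), with 134 to 363 CPM against 288 to 702 CPM. The phosphatase gene Alpl differed by -1.67 ± 0.60, the germ cell gene Dppa3 by 1.76 ± 0.64, the synaptonemal complex gene Syce1 by 3.16 ± 1.14 and Pcgf5 by -1.83 ± 0.72, none past the threshold. Piwil4 had 1 count in XX and 2353 in XY sums, from E11.5 and E12.5. The other lists had adjusted p from 0.374 to 0.994, with X-linked genes at 0.374 (514 genes, 2 lower adjusted over the list alone), escape genes and gut markers at 0.374, imprinted genes at 0.457 and male germ cell differentiation at 0.555. Of 13263 genes, edgeR called 0, with 673 at an unadjusted p under 0.05, and DESeq2 called 643 (108 higher and 535 lower in XY PGCs). Without E9.5, 5 genes passed, Epg5, Jmjd1c, Mx2 and Pcyt1b lower and Uba1y higher in XY PGCs, and without E10.5, or without all doubted libraries, Eif2s3y alone (adjusted p = 0.0124 and 7.72e-05, in a range of 8.59e-06 to 1 over the alternatives). These were chosen after their values were seen.

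The change per day differed between XY and XX PGCs for Y-linked genes (camera adjusted p = 0.00153; adjusted p = 0.377 with an estimated correlation), which climbed relative to XX PGCs, with Eif2s3y at 3.26 ± 1.14 more per day. That call was lost without E9.5 (adjusted p = 0.170) and without the 9 XX-labelled libraries with at least 20 Y-linked counts and 10 CPM (0.119). The other lists had adjusted p from 0.0681 to 0.999. Male germ cell differentiation, at 0.0681, passed without E9.5 (adjusted p = 3.06e-04, range 3.06e-04 to 0.556) with a larger gain in XY PGCs. Endothelium, at 0.0966, passed without E11.5 (0.0208, range 0.0208 to 0.972), and stress genes passed without E12.5 (0.0274, range 0.0274 to 0.972). X-linked genes passed in no alternative (adjusted p 0.0936 to 0.972). Of 13263 genes, edgeR called 0, with 552 at an unadjusted p under 0.05, and DESeq2 called 507 (235 and 272). Adjusted over the list alone, the cohesin gene Stag3 passed among meiotic genes (4.62 ± 1.21), with 0.0194 and 168 CPM in XY PGCs of E9.5 and E12.5 and 49.6 and 173 CPM in XX PGCs. The Nodal inhibitor genes Lefty1 (6.56 ± 2.16) and Lefty2 (5.92 ± 2.03) stood at 224 and 247 CPM in XY and 1.78 and 26.9 CPM in XX PGCs of E12.5 but did not pass (adjusted p = 1 each over all genes tested). At E10.5 Lefty2 stood at 236 CPM in XX and 0.190 CPM in XY PGCs.

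At E12.5, 47.5% of X-linked pairs were biallelic in 129C XX PGCs (396 of 833 pairs, exact 95% interval 44.1 to 51.0%) and 39.7% in C129 XX PGCs, but relative to the autosomal genes of the same cells, at 61.2 and 50.8%, the shares were alike at 0.777 and 0.782. The means over cells were 47.4% (SD over cells 13.5) and 43.2% (SD 18.98), and their difference was not tested. X-linked expression was lower in XO PGCs than in XX PGCs of either label. These comparisons have 1 sum on each side and no test. Over 191 X-linked genes, the median log2 ratio of XO to 129C XX PGCs was -0.84, against -0.047 for autosomal genes. It lay below all 10000 random lists of autosomal genes. The 9 escape genes had a median of -1.23 (percentile 1.46 among lists of autosomal genes), and they were not tested against other X-linked genes. The histone demethylase genes Kdm6a and Kdm5c had XO to XX ratios of 0.0878 (0.0709 to 0.108) and 0.122, Eif2s3x 0.206 (0.194 to 0.219), Usp9x 0.364, Ddx3x 0.487 (0.471 to 0.504) and Pbdc1 0.832. With mean CPM over cells these were 0.133, 0.195, 0.231, 0.675, 0.422 and 1.01 in the same order. For Kdm6a, 1 cell held 94.4% of the XX and all of the XO counts. Of the others, Car5b stood at 0.133, 5530601H04Rik at 0.375, Utp14a at 0.418, Xist at 0.788, 1810030O07Rik at 0.880 and Shroom4 at 1.14 (0.354 with mean CPM). Jpx at 2.03 and Ftx at 40.5 were higher in XO PGCs on 2 and 24 counts from 1 cell each. Against C129 XX PGCs the X-linked median of XO PGCs was -0.67, with -0.17 for autosomal genes. The X-linked median of 129C over C129 XX PGCs was 0.026, with -0.20 for autosomal genes (percentile 98.5), a gap of 0.23 that was 0.045 with mean CPM over cells. Glycolysis genes had a median of -0.72 there (percentile 1.11), and Xist a ratio of 0.458 (0.317 to 0.650).

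Among single genes, the imprinted transcript H19 had 2 counts in XO PGCs and 13380 in C129 XX PGCs, where 20 of 20 cells expressed it (1100-fold, counting interval 304.5 to 9084; 418-fold with mean CPM over cells). The X-linked genes Rpgr, of the photoreceptor cilium, and Usp11, a deubiquitinase, were lower in XO than in C129 XX PGCs by 777-fold (139.3 to 3.07e+04) and 566-fold (101.6 to 2.24e+04) on 1 count each, and by 268.5- and 291.5-fold with mean CPM. Both were detected in 18 of 20 XX cells, and Vps51 and Mars2 followed, with 66.2 and 74.8% of the XX counts from 1 cell. Higher in XO PGCs were Ndrg1, Wbp2nl, Slc41a2, Pak6 and Ubqln2, each with at least 92.6% of its XO counts from 1 cell. Against 129C XX PGCs, Zfp51 had 0 counts in XO PGCs, at least 980-fold lower with 96.3% of the XX counts from 1 cell. Rpgr (1197-fold, 214.8 to 4.73e+04; 282.5-fold with mean CPM, 81.2% of the XX counts from 1 cell), Ric1, Tia1 and Nrros were lower on 1 count each, the last 3 with at least 91.3% of their XX counts from 1 cell. Zfp948, Muc19, Cabyr, Wbp2nl and Tdgf1 were higher in XO PGCs, each with at least 78.6% of its XO counts from 1 cell. Between the strain labels, Lig4, which joins DNA ends, had 3354 counts in 129C XX PGCs, 99.4% of them from 1 cell, and 1 count in C129 XX PGCs (4025-fold, 722.0 to 1.59e+05; 1.24e+04-fold with mean CPM). Pdzd2, 2010300C02Rik, Ago4 and Rasgrp1 were also higher in 129C, each with at least 80.4% of its 129C counts from 1 cell. The DNA repair gene Bard1 was 29.1-fold higher in C129 XX PGCs (24.5 to 34.8, in 18 of 20 cells; 7.92-fold with mean CPM). Dgkq, Tgfa, Mid1ip1 and Cbl were higher there too, with 47.9 to 76.0% of their C129 counts from 1 cell.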

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

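The tests of technical explanations given here and the counts of other splits were chosen after the results were seen, while the comparisons of single cells with their group followed a fixed rule. In 28 comparisons of the cells of a group, for Xist, Y-linked counts, biallelic X-linked genes or the X-linked share of counts, 12 found a cell that stood apart from the others. These comparisons ran in groups of 5 to 9 cells and in none of the XX PGC groups of 18 or 20 cells. In the latter, Xist reached 105 CPM in XX PGCs of E11.5, where the median was 0.0752 CPM. Chance gives about 1 in 20 among normal values, which CPM and shares with many zeros are not, so the number 12 is not set against chance; where all other cells stand at 0 the rule has to single out the remaining one.

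Counts of 4 Y-linked genes stood in 55 of 90 XX-labelled libraries and reached 20 counts and 10 CPM in 9. Those in the XX PGC groups of 18 and 20 cells were not compared with their group, though XX PGCs of E9.5 reached 785 CPM over a median of 0.52. In the smaller groups 3 stood apart. The XX PGC replicate 14 of E10.5 had 47.4 CPM against 0 to 1.94 CPM in the other 7 cells, the XX somatic replicate 34 of E10.5 had 352.8 CPM against 0 to 0.134, and the XX somatic replicate 46 of E9.5 had 310.3 CPM against 0 to 0.834. In the 8 such libraries of E9.5 and E10.5, 0.535% of X-linked pairs were biallelic (3 of 561, exact 95% interval 0.110 to 1.55%), beside 0.175% in XY PGCs of these days (2 of 1146). So low a share came from 1.46e-04 of all choices of as many cells from the same groups (0.00389 for the 4 without uneven autosomes). These choices treat cells as independent, while the labels name no embryo. They may therefore make the result look rarer than it is where libraries share an embryo. Cells of XY embryos under an XX label may account for the 8 libraries. The XX PGC replicate 12 of E12.5 had 47.2 CPM of these genes but biallelic X-linked pairs at 44.6% (25 of 56, exact 95% interval 31.3 to 58.5%), against at most 2.04% in any XY PGC, which argues against an XY cell under an XX label there. RNA of other cells stays open for all 9 libraries, and no biological explanation was tested.

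The XX PGC replicates 23, 24 and 25 of E9.5 and 23 of E10.5 resembled each other beyond the other cells, with Spearman correlations of 0.913 to 0.943 between their counts against at most 0.832 in other pairs. Autosomal allelic ratios, which differ from cell to cell, correlated at 0.546 to 0.761 in their 6 pairs, against a median of 0.156 and a highest value of 0.32 in 697 other pairs of E9.5 and E10.5. The overlap argues against separate cells of a like state, whose ratios would lie in the range of the other pairs. Identical counts would correlate at 1, so these libraries are not 1 set of counts deposited again. Shared cDNA or a copied library may account for the overlap, and the labels, which put these libraries on 2 days, leave open which.

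Autosomal allelic ratios of 13 of the 30 libraries of E9.5, all labelled XX, leaned to 1 allele on 3 to 8 autosomes. The ratio was high in 10 libraries, low in 3 and both in 0, and which parental allele either stands for is not given. The 13 were replicates 1 to 12 and 46 of E9.5, and the other replicates of that day had 0 uneven autosomes. Whether these numbers mark a batch or an embryo is not stated in the labels and was not tested. Replicates 1, 6, 8 and 46 also held the Y-linked counts named above. On autosomes that were uneven over every other gene, 84.03% of the 3807 genes in between leaned to the same allele (exact 95% interval 82.8 to 85.2%), which argues against chance from few informative genes. In 213 windows of 20 informative genes with a mean ratio over 0.9 or under 0.1 on every other gene, the genes in between leaned to the same side in 93.4% (92.3 to 94.4%), so the lean runs through neighbouring genes. Stretches of autosomes with 1 parental allele, as a cross other than an F1 would give, may account for it but stay open: the genes in between were biallelic in 12.21% (10.9 to 13.7%), less than the 33.5% of the other windows (32.6 to 34.4%) and more than the 0.368% of X-linked genes in PGCs with 1 X chromosome. Loss of RNA, with a median of 1992 informative genes in these libraries against 3383 in the others of E9.5, was not tested, and neither was a biological explanation.

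Other cells that stood apart are given as values. Xist stood at 9.13 CPM in the 129C XX PGC replicate 40 of E12.5 (others 0.0528 to 4.24) and at 0.654 CPM in the XX PGC replicate 2 of E10.5 (others 0 to 0.155). In XY PGCs it reached 4.12 CPM in replicate 4 of E10.5 (others 0 to 0.367) and 5.41 CPM in replicate 29 of E12.5 (others 0.383 to 2.22). The XX somatic replicate 38 of E10.5 had 783.8 CPM of Xist, while the other 4 cells had 0 to 23.9. Y-linked genes stood at 1397 CPM in the XY PGC replicate 37 of E12.5 (others 43.7 to 619). Biallelic X-linked pairs made up 1.28% in the XY PGC replicate 9 of E10.5 and 1.16% in replicate 22 of E9.5, with 0% in the others of each, and 1.26% in replicate 36 of E12.5 (others 0 to 0.578%). The change of Y-linked genes with day differed between XY and XX PGCs (camera adjusted p = 0.00153; adjusted p = 0.377 with an estimated correlation; 3.87e-04 to 0.170 over the alternatives at the preset correlation), and the call was lost without E9.5 and without the 9 XX libraries named above, with or without the other doubted ones.

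Other ways to divide the 8 sums within each day were set against the real lineage and genotype comparisons, and 8 such splits are too few for a share under 0.05. For PGCs against somatic cells, 1 split, the real one, gave 118 genes and the highest other 0, or 5 among all 32 splits that could be fitted. For XY against XX PGCs the real split gave 0 genes, so that all 8 give at least as many and the count decides nothing, and the highest other gave 1.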

How the results depend on the processing

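The alternatives that leave out doubted libraries, count every ratio of at most 0.85, draw autosomal pairs to the counts of X-linked pairs or take X-linked dosage from summed counts, 22 in all, were chosen after the data were seen, and the others before. No paired analysis was possible because replicate numbers count single cells and the summed groups carry none, and only the embryonic day paired groups, as a factor in the fits and in the permutation tests. Leaving out cells under 100000 counts removed 0 cells and therefore gave no value. Of the values that answer a comparison, 215 kept their direction and their side of the threshold or moved by less than their spread, 41 moved further, 1 lost its call and 1 changed sign. Among single genes and groups 3616 kept both, 142 gained a call, 82 lost one, all of them lineage genes, 32 moved and 84 changed sign with a call in neither fit. Among tests of single lists 726 kept both, 15 gained a call, 28 lost one and 96 changed direction. Of the latter, the change of blood cell markers with day was called in the alternative, up at an adjusted p of 0.00372 without E12.5 (range 0.00372 to 0.790), and that of stress genes was called as reported (0.0216) but not without E9.5. XX PGCs exceeded XY PGCs in biallelic X-linked pairs on 4 of 4 days in each alternative that kept the 4 days, by 18.3 to 29.3 points. Their excess over XX somatic cells ran from 16.02 to 19.9 points, with 3 of 4 days higher when ratios of at most 0.85 were counted, and from 23.6 to 23.95 points over the 3 days left without the E9.5 libraries of uneven ratios. With days left out in turn, the excess ran from 14.9 to 26.95 points over XY PGCs and from 12.5 to 23.6 points over somatic cells. The ratio of X-linked dosage ran from 1.19 to 1.23, with 3 of 4 days higher for the RPRT values, and from 1.18 to 1.28 with days left out. The smallest sum was that of somatic cells of E12.5 with 4599162 counts of 3 cells, and 65 lineage genes passed without that day; what depth limits was not tested. Except where fewer genes, days or libraries entered, the cause was not tested.

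DESeq2 gave the largest count in each comparison, with 1538 genes by day against 0 in edgeR, 2806 against 118 by lineage, 643 against 0 by genotype and 507 against 0 for the change with day by genotype. On mean CPM over cells, limma called 1 gene by day, with a pseudocount of 5 also 1, and 414 by lineage. With day as a factor 1 gene passed at E12.5 against E9.5. With the XY groups added 415 lineage genes passed. Without the 9 XX libraries that reach 20 Y-linked counts and 10 CPM, and without all doubted libraries, 1 genotype gene passed. Leaving out days in turn gave 61 (without E10.5) to 198 (without E11.5) lineage genes, 0 to 5 (without E9.5) genotype genes and 1 to 2 lists called for the change with day by genotype, and 2 such lists were called without the 4 alike libraries and without the 9 XX libraries with Y-linked counts. With an estimated correlation, 3 of 7 lists were called by day, and 0 of 9, 0 of 1 and 0 of 1 by lineage, genotype and change with day by genotype.

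Biallelic X-linked pairs of XX PGCs of E9.5, at 3.47% as reported, stood at 2.50% without known escape genes, 4.71% at a minor allele share of 0.10, 8.11% with every ratio of at most 0.85 and 6.01% without all doubted libraries. At E10.5 the share was 19.14% at ratios of at most 0.85 and 15.01% without all doubted libraries. That of E11.5 was 33.6% at a minor allele share of 0.10, 27.1% at 0.20 and 40.6% at ratios of at most 0.85, and it ran from 28.03% without replicate 19 to 31.3% without replicate 27. At E12.5 it was 43.7% at 0.10, 34.9% at 0.20, 51.6% at ratios of at most 0.85 and 43.2% as the mean of shares per cell. The percent of X-linked genes higher at E12.5 than at E9.5 was 74.4 with at least 3 informative cells and 97.7 with at least 8. The rho with mean CPM was 0.466 with at least 8 cells, and that with position 0.0011 with at least 3. The call of the former was lost, but 60 shifts allow no p below 0.0167. Beside the other relations this adjusts to 0.05, so the loss decides nothing. The X-linked minus autosomal median of 129C over C129 XX PGCs was 0.045 with mean CPM over cells.

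The following lists, none of them called as reported, turned the direction of their test, with the adjusted p there. With no filter these were by day DNA methylation enzymes (0.912), Y-linked genes (0.940) and endothelium (0.912), by lineage escape genes (0.983), by genotype stress genes (0.937) and blood cells (0.937) and for the change with day by genotype methylation-sensitive genes (0.769). DESeq2's size factors in edgeR turned by lineage cell cycle (0.878) and by genotype pluripotency network (0.989). Day as a factor turned DNA methylation enzymes (0.872), Y-linked genes (0.981), imprinted genes (0.866) and endothelium (0.991). Adding the XY groups turned by lineage escape genes (0.947), cell cycle (0.701), X-linked genes (0.845) and X-linked genes without Xist and escape genes (0.845). Without the 9 XX libraries with Y-linked counts, it was by day Y-linked genes (0.673) and endothelium (0.638) and by lineage X-linked genes (0.907) and X-linked genes without Xist and escape genes (0.907). Leaving these out turned by genotype pluripotency network (0.999), meiotic prophase (0.953) and supporting cells (0.953). Without the 4 alike libraries, it was by day DNA methylation enzymes (0.964) and for the change with day by genotype methylation-sensitive genes (0.622). Their omission turned by genotype pluripotency network (0.975), methylation-sensitive genes (0.975), glycolysis (0.975) and blood cells (0.975). Without all doubted libraries, it was by day DNA methylation enzymes (0.969), Y-linked genes (0.714) and endothelium (0.683) and by lineage escape genes (0.853) and stress genes (0.669). By genotype this omission turned pluripotency network (0.797), methylation-sensitive genes (0.716), meiotic prophase (0.797), cell cycle (0.832), glycolysis (0.797), blood cells (0.797) and neural cells (0.797). For the change with day by genotype it turned methylation-sensitive genes (0.509), meiotic prophase (0.951), X silencing factors (0.767) and gut (0.9997).

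Days left out in turn moved the adjusted p of lists that turned on at least 1 day over these ranges. By day they were DNA methylation enzymes (0.654 to 0.926), escape genes (0.277 to 0.814), Y-linked genes (0.433 to 0.935) and imprinted genes (0.456 to 0.952). Others by day were stress genes (0.00249 to 0.802), blood cells (0.00372 to 0.489), pluripotency network (0.0577 to 0.935), endothelium (0.615 to 0.981) and gut (0.0589 to 0.664). Among these, stress genes were called as reported and without E10.5 in the same direction. By lineage they were escape genes (0.776 to 0.956), X-linked genes (0.764 to 0.994), X-linked genes without Xist and escape genes (0.764 to 0.994) and stress genes (0.377 to 0.934). By genotype they were cell cycle (0.461 to 0.952), glycolysis (0.568 to 0.989), supporting cells (0.568 to 0.989) and endothelium (0.216 to 0.998). Further ones were pluripotency network (0.611 to 0.989), methylation-sensitive genes (0.611 to 0.989), meiotic prophase (0.611 to 0.989) and male differentiation (0.123 to 0.985), and X silencing factors (0.598 to 0.998), stress genes (0.340 to 0.989) and blood cells (0.598 to 0.989). For the change with day by genotype they were meiotic prophase (0.286 to 0.972), X silencing factors (0.542 to 0.972), escape genes (0.516 to 0.972) and stress genes (0.0274 to 0.972). The rest were blood cells (0.201 to 0.972), neural cells (0.580 to 0.972), mesenchymal markers (0.717 to 0.994) and gut (0.808 to 0.994).

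Single genes whose log2 change took the other sign, none of them called as reported, follow with their value. DESeq2 turned by lineage Eif2s3y (-0.13) and for the change with day by genotype Col5a1 (-0.30), DESeq2's size factors in edgeR turned by lineage Eif2s3y (-0.032), and the XY groups turned Nes (0.51). Day as a factor turned Hbb-bh1 (-7.43). With limma on mean CPM these were by day Hbb-bh1 (-0.15), Plvap (0.030) and Sox17 (-0.087), by lineage Eif2s3y (-0.51) and by genotype Kdm5d (-0.61) and Utf1 (0.15). For the change with day by genotype limma turned Brdt (-0.038), Col5a1 (-0.61), Ddx3y (-0.17), Egr1 (-0.010) and Flt1 (0.0092). It also turned Fosb (0.089), Hba-x (0.60), Hbb-y (1.26), Rspo1 (0.45) and Xist (-0.45). A pseudocount of 5 turned by day Sox17 (-0.10). Without the 9 XX libraries with Y-linked counts, the change with day by genotype turned for Kdm5d (-0.50). Leaving out all doubted libraries turned by day Cdh1 (0.17) and Ddx3y (-0.077), by lineage Alas2 (3.54) and by genotype Elavl4 (0.51), Fosb (0.26), Hbb-y (-0.23) and Ier3 (0.46). The change with day by genotype turned for Cdh1 (-0.64), Dnmt3b (-0.29) and Kdm5d (-0.27).

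Days left out in turn moved such genes by day from lowest to highest log2 value over Cdkn2b (-0.61 to 4.92), Ddx3y (-0.45 to 0.32), Dppa4 (-0.045 to 1.52), Fos (-2.94 to 0.53) and Hba-x (-0.011 to 2.43). More genes by day were Hbb-bh1 (-3.40 to 2.38), Krt8 (-2.06 to 1.21), Lefty1 (-0.45 to 5.22), Lefty2 (-0.75 to 4.80) and Piwil1 (-0.66 to 2.25). To these came Plvap (-1.07 to 1.46), Sox17 (-0.12 to 0.89), Uty (-1.93 to 3.44) and Wnt4 (-0.019 to 0.29). By lineage they were Alas2 (-8.52 to 1.48) and Eif2s3y (-0.26 to 0.93). By genotype they were Alas2 (-2.66 to 0.67), Hbb-bh1 (-0.75 to 0.26), Hbb-y (-0.80 to 1.202), Lefty2 (-6.41 to 1.36), Utf1 (-1.06 to 0.16) and Wnt4 (-0.75 to 0.22). For the change with day by genotype they were 1810030O07Rik (-3.96 to 2.26), Car5b (-2.15 to 0.68), Cdh1 (-1.26 to 1.76), Cdx2 (-4.36 to 0.26), Cldn5 (-0.34 to 4.66) and Ddit3 (-7.39 to 0.28). Next came Ddx3x (-0.50 to 0.12), Ddx3y (-0.20 to 3.30), Dnmt3b (-1.51 to 3.38), Egr1 (-3.80 to 1.48) and Erbb3 (-1.43 to 2.27). They were followed by Flt1 (-5.56 to 1.70), Hba-x (-1.14 to 2.94), Hbb-y (-0.99 to 3.15), Kdm5d (-0.31 to 6.35), Kdm6a (-2.03 to 1.01) and Pax6 (-0.87 to 2.87). The last were Prdm14 (-0.045 to 1.09), Rspo1 (-1.15 to 3.00), Tet1 (-0.081 to 1.76), Tuba3b (-1.06 to 3.99) and Xist (-0.10 to 0.81).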

Other observations

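Imprinted genes, which are read from 1 parental copy in most tissues, were chosen for an allelic reading after the data were seen, and no test was run on them. In PGCs of both genotypes, 15.7% of their pairs were biallelic at E9.5 (17 of 108, exact 95% interval 9.45 to 24%), 15.4% at E10.5 (6 of 39, 5.86 to 30.5%), 18.8% at E11.5 (21 of 112, 12 to 27.2%) and 27.7% at E12.5 (26 of 94, 18.9 to 37.9%). These intervals overlap, and autosomal genes of the same cells stood at 33.8, 38.7, 44.8 and 47.2%. At E9.5, Kcnq1ot1 and Impact gave 7 and 7 of the 17 biallelic pairs, and at E12.5 5 and 4 of the 26. The pooled share of E9.5, and with it the overlap, therefore rests mainly on these genes. Somatic cells stood at 12.5, 3.33, 6.98 and 6.06% of 24 to 43 pairs. The zinc finger gene Peg3 was biallelic in 0 of 11 PGCs at E9.5 and 3 of 8 at E12.5, and the amino acid transporter gene Slc38a4 in 0 of 19 and 2 of 7. Plagl1 stood at 0 of 8 PGCs at E11.5 and 4 of 15 at E12.5, and the untranslated transcript H19 at 1 of 11 at E9.5 and 3 of 12 at E12.5. Kcnq1ot1, an antisense transcript within Kcnq1, was biallelic in 7 of 11, 9 of 15 and 5 of 11 PGCs at E9.5, E11.5 and E12.5, where reads of the host gene cannot be told apart without strand. Impact was biallelic in 7 of 9, 5 of 10 and 4 of 6 PGCs of these days. Grb10, which restrains growth, was biallelic in 0 of 7 and 0 of 6 PGCs at E9.5 and E12.5, and Mest in 0 of 5 and 0 of 10 at E11.5 and E12.5.

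Somatic cells with 1 X chromosome devoted a share of counts to X-linked genes that was not below that of XX somatic cells. XY somatic cells stood at 4.34% at E11.5 (SD 1.45, 3 cells, 3.41 to 6.02%) and 4.34% at E12.5 (1 cell), and the XO somatic cell of E12.5 at 4.71%. XX somatic cells stood at 3.62% (SD 0.334), 3.38% (SD 0.405), 3.53% (SD 0.575) and 3.39% (SD 0.329) from E9.5 to E12.5. With 1 to 3 cells in the groups with 1 X chromosome, these values carry no test.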
